A study of Mus musculus with 6 samples.

How the data were processed

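Polyadenylated RNA was sequenced from 6 libraries of mouse pancreatic islet cells purified by flow cytometry, 2 for each of 3 sorted populations. Per the labels' protocols, islets were cultured overnight in medium with 5.5 mM glucose and 10% serum, dissociated with 0.25% trypsin, sorted into Trizol, and turned into libraries with the TruSeq RNA version 2 kit. The labels do not say how strand was counted. The mice carried a nuclear mCherry reporter driven by an Ins1 promoter, which marks cells that make insulin, and a Cre recombinase under the somatostatin promoter that switches on YFP in delta cells and their descendants. Islets of 10 to 12 animals were pooled by sex, so each population has a library from a male pool, numbered replicate 1, and a library from a female pool, numbered replicate 2. Nothing in the labels names separate cultures beyond these pools, and p-values measure the spread between the 2 libraries of each group, pooled over the 3 groups.

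The deposited table holds 1 RPKM value (reads per kilobase of gene per M reads) for each of 46959 gene symbols in each library. Per the submitters' processing notes, the tools were STAR 2.5, featureCounts and edgeR 3.14.0 on the mouse genome GRCm38.p4, with no order or settings. RPKM values are not counts, so no count model was used as the test, and the depth had to be worked out. Low values of a gene are whole multiples of the value of 1 read, and exon lengths from GENCODE M21, which also gave the gene types and the coordinates below, were matched to 44027 symbols. The denominators obtained this way were 21.6 and 20.5 M reads for the male and female beta libraries, 12.5 and 10.9 M for the transdifferentiated libraries, and 17.0 and 15.7 M for the delta libraries. With a tolerance of 0.01 read, between 83.4% and 86.4% of the values under 50 reads came out whole. Whether the authors corrected these denominators for composition is not given in the sources used here. For a gene of 1 kilobase, 1 read was worth 0.0464 RPKM in the deepest library and 0.0917 RPKM in the shallowest, and 3 reads were worth 0.139 and 0.275 RPKM, so values near these levels carry large counting error.

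The 27 symbols that a spreadsheet had turned into dates were left out. Genes at 1 RPKM or more in at least 2 of the 6 libraries were tested, which left 13022. Values were transformed to log2(RPKM + 1), and the 3 pairwise comparisons were fitted in 1 model over the 6 libraries with limma 3.58.1 in R 4.3.3 (limma-trend, 2-sided, Benjamini-Hochberg adjustment over the genes tested, adjusted p under 0.05). Fold changes below are on this scale, which understates the change of low genes. The edgeR and DESeq2 tests planned for the case of counts were not run, because the table holds RPKM. The calls were tested on simulated data: in the comparison of transdifferentiated with beta cells, 95% of 100 genes changed by 1 log2 unit and 99% of 100 changed by 2 were recovered among 13022 genes, with 13 false calls. In the comparison with delta cells the shares were 94% and 99%, with 9 false calls. The changed genes were drawn from those with a mean log2(RPKM + 1) above 1. The noise was independent and normal, at the spread estimated by the fit. No difference between beta and delta cells, pool effect or separate counting error was simulated, so these shares may not hold for the real libraries.

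Insulin transcripts take a large part of the beta libraries: Ins2 alone held 41.3% and 34.8% of the summed RPKM there, against 17.9% and 18.6% in the transdifferentiated libraries. This lowers the RPKM of other genes, and median-of-ratios factors were 0.788 and 0.875 for the beta libraries and between 1.09 and 1.13 for the other 4. The median log2 fold change over all tested genes was 0.32 in transdifferentiated against beta, -0.03 in transdifferentiated against delta and -0.36 in beta against delta cells, and values after median-of-ratios scaling are given where they matter.

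The series text says that the 3 populations came from the same islets, so the pools pair the libraries. Sample titles carry a token that differs between the groups and is not explained, so the pairing rests on that text and the stated sex. A sentence of the series text names alpha cells as the source of the double-positive cells, whereas the title, the labels and the Cre driver name delta cells, and the latter was followed. Over the tested genes, deviations from the group means correlated at 0.47 between beta and transdifferentiated, 0.24 between beta and delta, and 0.36 between transdifferentiated and delta libraries. The fit without a block is the main one and the fit with the pool as a block is an alternative.

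The gene lists, the rule for named genes, the tests and most alternatives were fixed before the data were examined. For each comparison the text draws its named genes from the 8 higher and 8 lower genes of largest fold change past the threshold with no overlap between groups (predicted genes left out), from a fixed panel of hormones and regulators, from up to 4 members of each list with the smallest adjusted p, and, for genes outside the range of beta and delta cells, from the 6 higher and 6 lower with the largest smaller fold change. Genes named outside this rule are said to be so. The 20 lists cover beta, delta, alpha and other endocrine identity, maturity, immature or disallowed beta-cell genes, exocytosis, G protein-coupled receptors, stress, growth and energy metabolism, and markers of acinar, ductal, endothelial, immune, mesenchymal and Schwann cells. Some genes are not reported here; they stayed in the fits and in the list tests. Lists with at least 5 tested genes entered camera with a preset inter-gene correlation of 0.01, adjusted over 48 list tests. The position of transdifferentiated cells between delta (0) and beta (1) was the median over genes of the relative distance on the log2 scale, per pool, with genes chosen at 4-fold or more in the other pool. Alternatives changed the pseudocount, filter, scaling, intensity trend, block, libraries and set test. After the data were seen, limma-voom on reads worked out from RPKM for the 8818 tested genes whose reads came out whole in all 6 libraries was added, together with the main test on those genes, a scaled linear position, simulations that keep the real beta and delta levels, and a filter on the beta and delta libraries alone. The library sizes given to limma-voom included the median-of-ratios factors. Python 3.11.15 was used to read the table and for plots.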

Results

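The data are RPKM values of 6 libraries from adult mouse islets: beta cells (mCherry-positive), delta cells (YFP-positive) and double-positive cells that carry both the insulin reporter and the delta-cell lineage label, called transdifferentiated in the labels. Each group has 2 libraries, 1 from a male and 1 from a female pool of animals, with denominators of 10.9 to 21.6 M reads. The design asks how cells with both the delta-cell lineage label and the insulin reporter compare with beta cells and with delta cells of the same islets. Levels below are mean RPKM ± SD (n = 2 libraries) and fold changes are log2 values with their standard error (SE) and adjusted p from limma. The labelled sexes matched the sex-linked genes: Xist was at 23.7, 194 and 129 RPKM in the female beta, transdifferentiated and delta libraries and at 0.158 RPKM or less in the male ones. Ddx3y, Eif2s3y, Kdm5d and Uty were at 1.11 RPKM or more in the male libraries and at 0.0353 RPKM or less in the female ones.

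Beta and delta cells, the 2 reference populations, differed widely in their hormones and in regulators of their identity. Ins2, one of the 2 mouse insulin genes (chromosome 7, 142678656 to 142743381, GRCm38), was at 206321 ± 52300 RPKM in beta and 1247 ± 172 RPKM in delta cells. The log2 fold change was 7.35 (SE 0.20, adjusted p = 3.71e-06). Ins1 was higher by 7.44 (SE 0.19). The 2 insulin transcripts are near-identical, so the split of reads between them is uncertain. Somatostatin (Sst, chromosome 16, 23889573 to 23890958) was at 79.0 ± 11.1 RPKM in beta and 54125 ± 6160 RPKM in delta cells, a log2 fold change of -9.40 (SE 0.15, adjusted p = 9.04e-07). Ucn3, a peptide of mature beta cells, G6pc2, a glucose-6-phosphatase subunit, and Mafa, a beta-cell transcription factor, were higher in beta cells by 6.85, 6.29 and 6.28, as were the granule protein Sytl4 (5.77), Prss53 (5.57) and the respiratory subunit Cox6a2 (5.19). Rbp4, a retinol carrier, Hhex, a delta-cell transcription factor, the arginase Arg1, Peg10, the growth-associated gene Gap43 and Cd24a were lower in beta cells, at -7.58, -7.06, -7.02, -5.995, -5.83 and -5.82. The delta libraries also held the transcripts of other islet hormones: Gcg (glucagon) was at 15209 ± 900 RPKM, Ppy (pancreatic polypeptide) at 16276 ± 649 RPKM and Pyy (peptide YY) at 20511 ± 1057 RPKM, against 329 ± 132, 426 ± 136 and 254 ± 36.5 RPKM in beta cells.

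**Figure D1:**
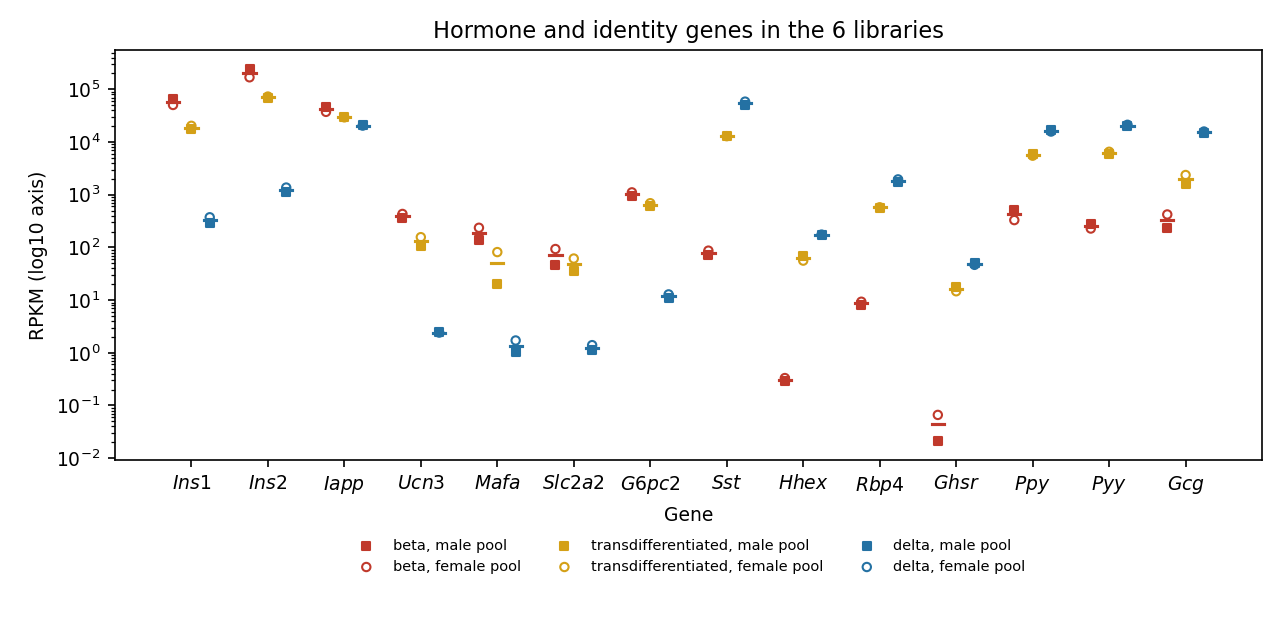
RPKM (log10 axis) of 14 hormone and identity genes in each library, with filled squares for male pools, open circles for female pools and a bar at the mean of each group of 2. For Ins2, Ucn3, Sst, Hhex, Ppy, Pyy and Gcg, both transdifferentiated libraries lie between the beta and the delta libraries.

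Of 13022 genes tested between beta and delta cells, 7546 passed the threshold, 1521 higher and 6025 lower in beta cells. After median-of-ratios scaling, which moves the median log2 fold change from -0.36 to -0.02, the split was 3623 higher and 3865 lower, so 48.4% in place of 20.2% of the calls were higher in beta cells. Without delta replicate 1 or 2 the genes higher in beta cells fell to 853 or 926. Of the fixed lists, beta identity had 16 of 17 members higher (17 of 17 adjusted over the list alone), with Nkx6-1 at 3.89 (SE 0.23) and Slc2a2, a glucose transporter, at 4.91 (SE 0.36). Its camera adjusted p was 9.06e-21 (adjusted p = 0.21 with an estimated correlation). The remaining member, Pdx1, differed by 0.54 (SE 0.20, adjusted p = 0.052), and passed with the pool as a block (adjusted p = 0.0093), after scaling (adjusted p = 0.0051) and without beta replicate 1 (0.77, adjusted p = 0.021). The maturity and glucose-sensing list had 11 members higher and 3 lower of 18 (camera adjusted p = 1.33e-08, and adjusted p = 0.41 with an estimated correlation), with the fatty acid receptor Ffar1 at 4.37 and the cation channel Trpm5 at 3.40. Delta identity had 10 of 10 members lower (camera adjusted p = 3.09e-07, and adjusted p = 0.21 with an estimated correlation), among them Ptprz1 at -4.72 and the ghrelin receptor Ghsr at -5.56. Alpha identity had 8 of 9 members lower in beta cells (camera adjusted p = 0.0077, and adjusted p = 0.41 with an estimated correlation), with the alpha-cell regulators Irx1 and Irx2 at -2.66 and -2.45.

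Other groups separated beta from delta cells as well, with the same counts adjusted over the list alone unless given. Oxidative phosphorylation genes were mostly higher in beta cells, 13 of 20 against 1 lower (camera adjusted p = 8.09e-08, and adjusted p = 0.32 with an estimated correlation), with Cyc1 at 0.92, Cox5a at 0.94 and Sdhb at 0.74. Glycolysis had 2 of 14 members higher, Gapdh (0.76) and Pkm (0.73), and 0 adjusted over the list alone (camera adjusted p = 0.0022, and adjusted p = 0.71 with an estimated correlation). With the pool as a block 10 were higher and 1 lower, and without beta replicate 1 the list's adjusted p was 0.11, that of Gapdh 0.14 and that of Pkm 0.17. Both genes also lost their calls without delta replicate 2 (adjusted p = 0.17 and 0.19), and reads of Gapdh can be shared with its pseudogenes. Immune genes had 10 of 12 members higher in beta cells and 1, C1qa, lower (11 and 1 adjusted over the list alone, camera adjusted p = 2.11e-10, and adjusted p = 0.21 with an estimated correlation). After scaling 11 were higher and 0 lower, and C1qa did not pass (-0.41, adjusted p = 0.062). Acinar genes had 1 of 12 called, Bhlha15 at 0.66 (SE 0.24, adjusted p = 0.0496), and 0 adjusted over the list alone, with a camera adjusted p of 0.0082, 0.71 with an estimated correlation, 0.24 after scaling and 0.37 without beta replicate 1. With the pool as a block 2 acinar genes were higher and 1 lower. Bhlha15 missed the threshold without any 1 library except beta replicate 1 (adjusted p between 0.075 and 0.16). Acinar transcripts were at very different levels in the 2 pools. Ctrb1, a chymotrypsinogen named outside the rule for named genes, was at 3429 RPKM in the male and 135 RPKM in the female beta library, 915 and 34.2 RPKM in the transdifferentiated libraries, and 271 and 157 RPKM in the delta libraries.

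Immediate early genes had 9 of 14 members lower in beta cells, with Jun at -2.39, Ier2 at -2.11, Zfp36 at -1.59 and Egr1 at -3.15 (camera adjusted p = 0.15, 0.80 with an estimated correlation, 0.041 after scaling and 0.024 without delta replicate 2). Immature or disallowed beta-cell genes had 8 of 10 lower, with Neurog3, the endocrine progenitor factor, at -5.17, Acot7 at -2.49 and Cat at -1.20. The camera adjusted p of that list was 0.075, 0.41 with an estimated correlation, 0.048 with the pool as a block, 0.015 after scaling and 0.017 without delta replicate 1. The G protein-coupled receptor list had 10 members higher and 9 lower of 23, with Ffar4 at -4.66 and the somatostatin receptor Sstr1 at -4.05. Its camera adjusted p was 0.053, 0.77 with an estimated correlation, 0.048 with the block, 0.043 without beta replicate 2 and 0.0498 without delta replicate 1. Its median was -0.02 and 0.10 after scaling. The pan-endocrine (5 higher, 5 lower of 15), exocytosis (4 and 5 of 15, 5 and 6 adjusted over the list alone, 5 and 7 with the block), endoplasmic reticulum stress (5 and 5 of 15), ductal (1 and 3 of 7, 2 and 3 with the block) and proliferation (0 and 1 of 5) lists did not pass camera. After scaling the splits were 7 higher and 4 lower, 5 and 3, 7 and 1, 1 and 2, and for proliferation 3 and 0, the opposite way. Medians of the first 4 were below 0 (-0.27, -0.33, -0.15 and -0.09) and above 0 after scaling (0.16, 0.08, 0.28 and 0.34), where camera leaned up in both. The mean of exocytosis genes was 0.13. In these lists Chga was higher by 1.48, Trib3 by 2.01, Atf4 by 0.53, Asns by 0.81, Syt13 by 0.82 and Krt7 by 1.11, while Isl1, Rfx6, Chgb, Stx1a, Cplx2, Hsp90b1, Sox9 and Muc1 were lower in beta cells. Mcm6 was at -0.61 and lost its call after scaling and without delta replicate 1 or 2 (adjusted p = 0.16, 0.070 and 0.082). Of lists with fewer than 5 tested genes, Ppy and Pyy and the endothelial genes Esam and Egfl7 were lower in beta cells. After scaling the adjusted p of Esam was 0.072 and that of Egfl7 0.14. Egfl7 also missed the threshold without beta replicate 2, delta replicate 1 or delta replicate 2 (adjusted p = 0.15, 0.061 and 0.13). No mesenchymal marker passed the filter.

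Transdifferentiated cells, compared with the delta cells whose lineage label they carry, had higher beta-cell transcripts and lower delta-cell transcripts. These are differences between sorted populations, and no change over time was measured. Ins2 was at 70625 ± 3387 RPKM against 1247 ± 172 RPKM in delta cells, a log2 fold change of 5.83 (SE 0.20, adjusted p = 6.38e-05). Ins1 was higher by 5.82 (SE 0.19, adjusted p = 5.64e-05). The double-positive cells were sorted on a reporter driven by an Ins1 promoter, so higher insulin RNA than in delta cells is in part selected by the sort. G6pc2, Ucn3, Sytl4, Slc2a2, Mafa, the prolactin receptor Prlr and Nkx6-1 were higher by 5.65, 5.25, 4.85, 4.40, 4.17, 4.01 and 3.22. Sst was lower by 2.07 on the log2 scale (SE 0.15, adjusted p = 8.12e-04), at 12887 ± 64.2 RPKM. Rbp4, Hhex and Ghsr were lower by 1.70, 1.47 and 1.51. The lower genes with the largest changes were Gcg (-2.96, SE 0.29, adjusted p = 0.0021), Pdk4, an inhibitor of pyruvate oxidation (-2.16), Eef1a2 (-2.12), Irx1 (-2.07), Sst, Peg10 (-2.03), Ly6h (-1.96) and Edn3 (-1.92). Pyy and Ppy were at -1.71 and -1.52. Which cells of the YFP-positive sort the Gcg, Irx1, Ppy and Pyy RNA of the delta libraries came from was not tested. Their lower values therefore need not be a trait of transdifferentiated cells. Iapp, the amylin gene, differed by 0.52 (SE 0.14, adjusted p = 0.067) and Pdx1 by 0.19 (SE 0.20, adjusted p = 0.61), which was -0.02 without transdifferentiated replicate 2. Ppy had an adjusted p of 0.063 without transdifferentiated replicate 2.

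Of 13022 genes, 1657 passed: 720 higher and 937 lower in transdifferentiated cells. This count depends on each of the 4 libraries compared: it was 759 without transdifferentiated replicate 1, 655 without replicate 2 of that group, 717 without delta replicate 1 and 522 without delta replicate 2. Of the 720 higher genes 496 were also higher in beta than in delta cells, where independent lists of these sizes would share 84.1. Of the 937 lower genes 909 were also lower in beta than in delta cells, against 434. Simulated groups with no effect shared at most 1 gene in either direction in 20 runs, a value that leaves out the real effects. With the beta and delta levels kept and the transdifferentiated effects dealt to other genes at random, the shared higher genes were 240 on average where independent lists gave 213, and the lower ones 917 against 860. These simulated lists were longer than the observed ones, with 1531 higher and 1722 lower genes on average against 720 and 937, so each overlap is to be read beside its own independent value. Part of the excess may come from the delta libraries that both comparisons use.

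By list, beta identity had 15 of 17 members higher (16 adjusted over the list alone, camera adjusted p = 1.44e-22, and adjusted p = 0.21 with an estimated correlation). Maturity and glucose sensing had 11 of 18 higher and 0 lower (camera adjusted p = 2.16e-11, and adjusted p = 0.34 with an estimated correlation), with Ffar1 at 3.73. Delta identity had 9 of 10 lower (10 adjusted over the list alone, camera adjusted p = 6.75e-11, and adjusted p = 0.21 with an estimated correlation), with Ptprz1 at -1.37 and the fatty acid receptor Ffar4 at -1.41. Alpha identity had 8 of 9 lower (8 lower and 1 higher adjusted over the list alone, camera adjusted p = 1.73e-06, and adjusted p = 0.21 with an estimated correlation), among them Ttr at -1.62. The limit given above for Gcg and Irx1 applies to this list too. Immature or disallowed beta-cell genes had 4 of 10 lower (5 adjusted over the list alone, 6 with the pool as a block, camera adjusted p = 4.88e-04, and adjusted p = 0.21 with an estimated correlation), with Neurog3 at -1.49 and Acot7 at -1.48. Immediate early genes had 3 of 14 lower, Ier2 at -1.11, Jun at -0.89 and Junb at -1.02 (camera adjusted p = 0.023, and adjusted p = 0.67 with an estimated correlation). That list's adjusted p was 0.31 without delta replicate 1. The calls of Jun and Junb were lost without transdifferentiated replicate 1 or delta replicate 1 or 2 (adjusted p of Jun 0.13, 0.15 and 0.059, of Junb 0.14, 0.16 and 0.17). Jun also missed it without transdifferentiated replicate 2 (adjusted p = 0.14), and Ier2 without transdifferentiated replicate 1 (adjusted p = 0.0504).

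Receptors went both ways, with 10 of 23 higher and 6 lower (11 and 8 adjusted over the list alone). The galanin receptor Galr1 (2.84), the GABA receptor subunit Gabbr2 (3.195) and the short-chain fatty acid receptor Ffar3 (2.17) were higher than in delta cells. Camera did not call this list (adjusted p = 0.14, and 0.80 with an estimated correlation), except without transdifferentiated replicate 1 (0.048) or delta replicate 2 (0.049). Pan-endocrine genes (3 higher, 1 lower of 15, and 3 and 2 adjusted over the list alone), exocytosis genes (3 and 1 of 15, 3 and 2 adjusted over the list alone, 3 and 3 with the pool as a block) and stress genes (1 and 2 of 15, 2 and 4 adjusted over the list alone, 3 and 3 with the block) did not pass, and of their members Syt4, a granule synaptotagmin, was higher by 1.10 (SE 0.14, adjusted p = 0.0045). Oxidative phosphorylation (20 tested), glycolysis (14), acinar (12) and proliferation (5) genes had 0 members past the limma threshold in this comparison, also adjusted over the list alone and after scaling. With the pool as a block 1 glycolysis gene was higher and 1 lower. Sox9 was the 1 ductal gene called (-0.92). It missed the threshold without transdifferentiated replicate 1 or delta replicate 2 (adjusted p = 0.10 and 0.12). Adjusted over the list alone 1 ductal gene was higher and 2 lower. C1qa was the 1 immune gene called (-1.10), with adjusted p = 0.054 without transdifferentiated replicate 1 and 0.052 without delta replicate 2. Camera called the immune list higher only without transdifferentiated replicate 1 (adjusted p = 0.015, where the list had 0.37 with all libraries and 0.81 with an estimated correlation). The 2 endothelial genes tested did not pass. Median and mean differed in sign for receptors (-0.0095 and 0.50), exocytosis (-0.12 and 0.29), acinar genes (0.11 and -0.05) and glycolysis (0.01 and -0.01), and camera leaned up for oxidative phosphorylation at a median of -0.05.

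Compared with beta cells, transdifferentiated cells held more delta-cell transcripts and less insulin RNA. Sst was at 12887 ± 64.2 RPKM against 79.0 ± 11.1 RPKM, a log2 fold change of 7.34 (SE 0.15, adjusted p = 4.75e-06). The sort also used the label set by somatostatin-promoter Cre, so higher Sst than in beta cells may in part be selected. Rbp4 (5.88), Hhex (5.59), Arg1 (5.34), Pyy (4.63), Cd24a (4.30), Mir344-2 (4.24), Mest (4.23), Ghsr (4.04) and Ppy (3.77) were higher as well. Mir344-2, a microRNA gene, was at 30.5 ± 13.6 RPKM in transdifferentiated and 0.595 ± 0.0223 RPKM in beta cells. It is so short that few reads lie behind its values. Ins1 was lower by 1.61 (SE 0.19, adjusted p = 9.25e-04), Ins2 by 1.52 (SE 0.20, adjusted p = 0.0015) and Ucn3 by 1.60 (SE 0.19, adjusted p = 9.73e-04). Mafa was lower by 2.11 (SE 0.59, adjusted p = 0.023), G6pc2 by 0.64 (SE 0.14, adjusted p = 0.0089), Nkx6-1 by 0.67 (SE 0.23, adjusted p = 0.047) and Iapp by 0.49 (SE 0.14, adjusted p = 0.028). Pdx1 (-0.35, adjusted p = 0.18, and 0.015 after scaling) and Slc2a2 (-0.50, adjusted p = 0.27) did not pass. The 8 lower genes with the largest changes were mostly immune or antigen-presentation genes: Cd74 (-3.85, SE 0.35, adjusted p = 4.17e-04), the class II histocompatibility genes H2-Eb1 (-3.64), H2-Aa (-3.46) and H2-Ab1 (-3.26), the cathepsin Ctss (-3.38), Apoe (-3.30), C1qb (-3.00) and the lysozyme Lyz2 (-2.87). Cd74 was at 73.2 ± 0.972 RPKM in beta and 4.60 ± 3.15 RPKM in transdifferentiated cells. Gcg was higher by 2.63 (SE 0.29). Without transdifferentiated replicate 1 the adjusted p of G6pc2 was 0.066, that of Mafa 0.059, that of Nkx6-1 0.25 and that of Iapp 0.15. Mafa also missed the threshold without beta replicate 1 or 2 (adjusted p = 0.052 and 0.11). Nkx6-1 did so without beta replicate 2 or delta replicate 1 or 2 (adjusted p = 0.19, 0.077 and 0.077), and Iapp did so without beta replicate 1, transdifferentiated replicate 2, delta replicate 1 or delta replicate 2 (adjusted p = 0.15, 0.16, 0.057 and 0.073).

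Of 13022 genes, 6642 passed, 5540 higher and 1102 lower in transdifferentiated cells. After median-of-ratios scaling, which moves the median from 0.32 to -0.002, the split was 3624 and 3395, so 51.6% in place of 83.4% of the calls were higher. Without transdifferentiated replicate 1 the count was 4132, with 410 lower, and without replicate 2 of that group 697 were lower. Of the 5540 higher genes 4844 were higher in delta than in beta cells, where independent lists would share 2563. Of the 1102 lower genes 813 were lower in delta than in beta cells, against 129. Simulated groups with no effect shared at most 1. With the effects dealt to other genes at random, 3108 were shared where independent lists gave 3048, and 226 against 187, in lists of 6103 higher and 1340 lower genes on average. Part of the excess may come from the beta libraries that both comparisons use.

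**Figure D2:**
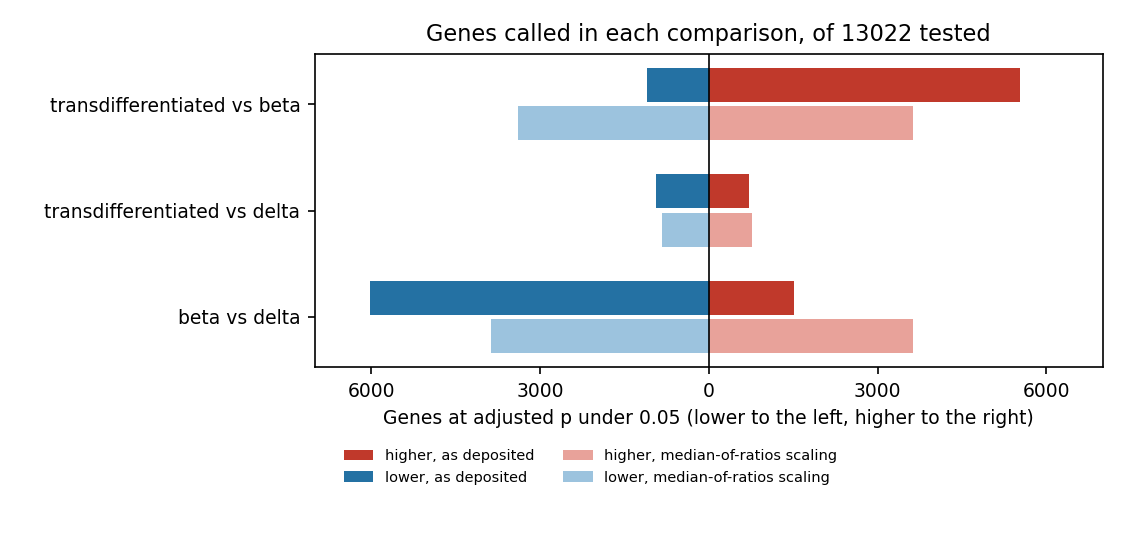
Number of genes at adjusted p under 0.05 in each comparison (horizontal axis, lower to the left and higher to the right), with RPKM as deposited in dark and after median-of-ratios scaling in light colours. Scaling changes the 5540 higher and 1102 lower genes of transdifferentiated against beta cells to 3624 and 3395.

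By list, with the same counts adjusted over the list alone unless given, beta identity had 9 of 17 members lower and 0 higher (13 lower after scaling, camera adjusted p = 1.55e-08, and adjusted p = 0.32 with an estimated correlation), with Trpm5 at -1.26. With the pool as a block 11 were lower and 1 higher. Maturity and glucose sensing had 8 of 18 lower, such as the pyruvate carboxylase Pcx (-1.03), and 4 higher, such as Esrrg (0.72), of which 1 remained higher after scaling (camera adjusted p = 5.58e-04, and adjusted p = 0.67 with an estimated correlation). Oxidative phosphorylation had 12 of 20 lower (12 lower and 1 higher adjusted over the list alone, 19 lower after scaling, camera adjusted p = 3.58e-10, and adjusted p = 0.26 with an estimated correlation), with Cox5a at -0.89, Sdhb at -0.71, Cyc1 at -0.70 and Ndufb8 at -0.69. Endoplasmic reticulum stress had 6 of 15 lower and 1 higher (9 and 1 after scaling, 7 and 2 with the block, camera adjusted p = 0.0025, and adjusted p = 0.21 with an estimated correlation), with Trib3 at -1.07, Chac1 at -0.70 and Atf4 at -0.42 and the chaperone Hsp90b1 at 1.002. The calls of Trib3 and Atf4 were lost without transdifferentiated replicate 2 (adjusted p = 0.071 and 0.077), that of Trib3 also without beta replicate 1 (adjusted p = 0.05005) and that of Atf4 without transdifferentiated replicate 1 (adjusted p = 0.063). Immune genes had 11 of 12 lower (camera adjusted p = 5.27e-14, and adjusted p = 0.21 with an estimated correlation). Delta identity had 10 of 10 higher (camera adjusted p = 3.29e-07, and adjusted p = 0.21 with an estimated correlation).

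Glycolysis had 0 of 14 members called by limma, at a median of -0.45 (camera adjusted p = 4.88e-04, adjusted p = 0.67 with an estimated correlation, and 0.087 without beta replicate 1 and 0.055 without transdifferentiated replicate 2), and with the pool as a block 8 were lower and after scaling 4. Acinar genes had 0 of 12 called, at a median of -1.89 (camera adjusted p = 0.0027, adjusted p = 0.67 with an estimated correlation, 0.22 after scaling, 0.36 without beta replicate 1 and 0.14 without transdifferentiated replicate 2), and 2 were lower with the block. Immediate early genes had 8 of 14 higher, with Nr4a1 at 2.14, Fosb at 1.90, Jun at 1.51 and Ier2 at 0.998. Alpha identity had 3 of 9 higher (5 with the block), Gcg, Irx2 (1.21) and Irx1 (0.59), of which Irx1 missed the threshold without beta replicate 1 or transdifferentiated replicate 2 (adjusted p = 0.081 and 0.088). Immature or disallowed genes had 4 of 10 higher, Pyy, Neurog3 (3.68), Acot7 (1.02) and Cat (0.79). Receptors had 11 of 23 higher and 5 lower, with Ffar4 at 3.24, Sstr1 at 2.60 and the muscarinic receptor Chrm4 at 2.06. Their median of 0.21 was -0.12 after scaling, with 9 higher and 8 lower. These 4 lists did not pass camera (adjusted p = 0.45, 0.44, 0.42 and 0.77). Pan-endocrine genes (5 higher, 2 lower of 15, and 4 lower with the block) had a median of -0.08 and a mean of 0.22. After scaling 5 were higher and 9 lower, at a median of -0.49, so the balance of calls turned. The named members were higher, with Rfx6 at 2.02, Isl1 at 1.84, Pax6 at 0.97 and Chgb at 0.87. Exocytosis genes (4 higher, 3 lower of 15, 3 and 5 after scaling) had a median of 0.15 and of -0.25 after scaling, with Snap25 at 1.25, Stx1a at 0.69 and Syt13 at -0.51. Ductal genes had 3 of 7 higher and 1 lower (1 and 1 after scaling, 3 and 2 with the block), with Sox9 at 1.20 and Krt7 at -0.65. Muc1 (0.64) lost its call after scaling (adjusted p = 0.15), without transdifferentiated replicate 1 (adjusted p = 0.15) and without beta replicate 2 (adjusted p = 0.11). The pan-endocrine, exocytosis and ductal lists did not pass camera (adjusted p = 0.28, 0.37 and 0.43), nor did proliferation (0 of 5 called, adjusted p = 0.39). Camera leaned down for receptors and exocytosis although their medians as deposited were above 0. Of 2 endothelial genes Esam was higher (0.46), a call lost after scaling (adjusted p = 0.39) and without transdifferentiated replicate 1 or 2 (adjusted p = 0.080 and 0.083).

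A set of genes lay outside the range of both reference populations: 226 were higher and 14 lower in transdifferentiated cells than in beta and in delta cells. Rgs11, a regulator of G protein signalling, was at 28.9 ± 5.90 RPKM in transdifferentiated cells, 8.14 ± 3.04 RPKM in beta cells and 3.73 ± 2.13 RPKM in delta cells. The antisense transcript 2410021H03Rik was at 44.0 ± 7.20, 11.4 ± 1.95 and 4.24 ± 0.444 RPKM. The microRNA gene Mir6955, the snRNA gene Gm25772, the snoRNA gene Gm26387 and the unclassified Gm43843 were at 5.26, 8.26, 3.29 and 4.43 RPKM in transdifferentiated cells and at or below 1.67 RPKM in the means of the others, and the first 3 are so short that few reads lie behind their values. Without strand, reads of 2410021H03Rik and its overlapping partner cannot be told apart. Short non-coding RNA genes were 45 of the 226 (19.9%, against 326 of the 13022 genes tested, Fisher's exact test p = 5.09e-28). Such genes can pass the filter on a few reads in the transdifferentiated libraries alone. Among 12414 genes that pass it in the beta and delta libraries alone, 16 of 143 were short (11.2%, against 179 of the 12414, Fisher's exact test p = 2.22e-10). The libraries were made from polyadenylated RNA, and reads at short genes were not told apart from those of overlapping transcripts. Neither test therefore shows that short RNAs themselves were higher in transdifferentiated cells. Of the 14 lower genes, Syndig1l was at 38.3 ± 0.876 RPKM against 57.8 ± 4.95 in beta and 58.3 ± 2.80 in delta cells, Vim at 0.843 ± 0.235 against 1.93 ± 0.385 and 2.75 ± 0.431. Cd36 was at 0.416 ± 0.00948 against 1.49 ± 0.262 and 1.23 ± 0.0880. Mpst, mt-Tq and the snRNA gene Gm27343 were also lower, the last 2 listed at 0 in both transdifferentiated libraries.

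Independent lists would share 306 higher and 79.3 lower genes, so both counts lie below that expectation, and simulated groups with no effect gave at most 1. With every transdifferentiated level set inside the range of the other 2 populations, 20 simulations gave 24.3 higher genes on average (37 at most) and 11.3 lower (16 at most). The 14 lower genes lie within what noise gave in this fit, so the genes named among them are uncertain. The same simulation gave at most 23 lower genes for the scaled fit, against 53, and at most 17 with the block, against 29. After scaling the counts were 195 and 53, and with the pool as a block 297 and 29. The 226 fell to 96 or 80 without transdifferentiated replicate 1 or 2 and to 146 or 72 without delta replicate 1 or 2. The 14 ranged from 2 without delta replicate 1 or 2, and 4 without transdifferentiated replicate 1, to 34 and 45 without beta replicate 1 or 2. Among the named genes the calls against delta cells of Vim (without transdifferentiated replicate 2 or delta replicate 1, adjusted p = 0.076 and 0.065), Gm26387 (without transdifferentiated replicate 2 or delta replicate 2, adjusted p = 0.060 and 0.056), and Cd36, Syndig1l, Mpst and mt-Tq (without any 1 of the 4 libraries compared, adjusted p between 0.072 and 0.31) were lost. So was that of Mpst without beta replicate 1 or 2 (adjusted p = 0.066 and 0.067). Against beta cells Rgs11 lost its call without transdifferentiated replicate 1 (adjusted p = 0.057), Vim without beta replicate 2 or transdifferentiated replicate 2 (adjusted p = 0.069 and 0.081), and Mpst without beta replicate 1 or 2 or transdifferentiated replicate 1 (adjusted p = 0.092, 0.085 and 0.18).

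Genes that distinguish beta from delta cells lay between the 2 in transdifferentiated cells. On the log2 scale the median position, where 0 is the delta and 1 the beta level, was 0.68 in the male and 0.65 in the female pool over beta-enriched genes (170 and 167 genes). It was 0.34 in both pools over delta-enriched genes (398 and 533 genes). The mean over the pools was 0.67 ± 0.024 for beta-enriched and 0.342 ± 0.00137 for delta-enriched genes (SD, n = 2). With 2 values no test was made. Between 81.2% and 93.5% of the genes lay between the levels of the 2 reference populations. On the linear RPKM scale the order turned, with 0.43 for beta-enriched and 0.58 for delta-enriched genes, and with 0.32 and 0.61 after scaling.

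**Figure D3:**
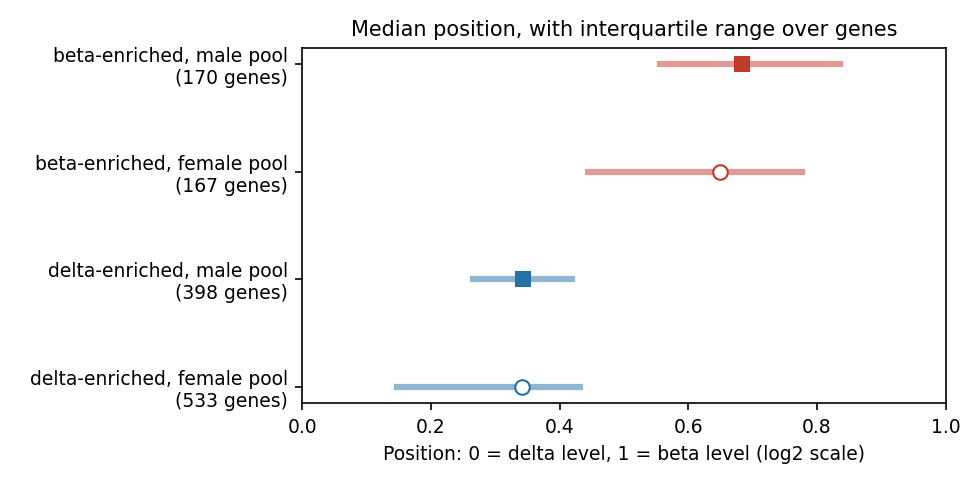
Median position of transdifferentiated cells between delta (0) and beta (1) on the log2(RPKM + 1) scale (horizontal axis), for beta-enriched and delta-enriched genes in each pool, with the interquartile range over genes as a line. Beta-enriched genes lie at 0.68 and 0.65, delta-enriched genes at 0.34 in both pools.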

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

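Among the genes that the rule for named genes gives for each comparison and that are reported here, 0 moved in opposite directions in the male and the female pool in that comparison. For genes chosen with no overlap between groups this was fixed in advance. Most others were chosen by their adjusted p, so the 0 is no test of agreement between the pools. Ctrb1, named outside that rule, moved in opposite directions: it was higher in beta (3429 RPKM) than in delta cells (271) in the male pool and lower (135 against 157) in the female pool. Against delta cells, transdifferentiated cells held more in the male pool (915 RPKM) and less in the female pool (34.2), and this difference was not tested. With 2 libraries per group, no search for a library far from the others of its group was possible.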

How the results depend on the processing

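The limma-voom fit, the main test on its genes and the scaled linear position were chosen after the data were seen. Directions and calls of the 194 called gene results held in 1843 of 1942 values from settings that kept all libraries; 46 results lost their call or direction in at least 1, 33 of them without a filter. Without a filter the fold changes stayed and the errors of hormone genes grew. Against beta cells Ins1 (adjusted p = 0.13), Ins2 (0.53), Mafa (0.084), Nkx6-1 (0.12) and Iapp (0.89) then lost their calls, as did Ins2 (0.13), Sst (0.071), Ppy (0.14) and Pyy (0.083) against delta cells. Quantile normalization also ended Ins1 (-0.39, adjusted p = 0.056) and Ins2 (0), the top gene of both groups, against beta cells. Nkx6-1 against beta cells also lost its call there (adjusted p = 0.099) and with a pseudocount of 0.1 (0.0503). It did so without the intensity trend (0.052) and with only the 4 libraries of the groups compared (0.077). Iapp had an adjusted p of 0.10 with only those 4 libraries. Leaving out a library ended 39 of the calls at least once. Quantile normalization, which gives every library the same top values, turned Iapp (0.39 against beta, and -0.20 for beta against delta), Irx1 (-0.20) and Esam (-0.0722), all against beta, and Egfl7 (0.0058, beta against delta). Pdx1 turned against delta without transdifferentiated replicate 2 (-0.0186); the cause was not tested. With fry, which tests against no change and so takes in the shifted median, the receptor list passed as higher against beta cells (adjusted p = 0.015), opposite to camera's uncalled direction. Of the other list results under fry, 35 stayed on the same side of the threshold, 6 lost their call and 6 gained one. Against beta cells, maturity and glucose sensing was lost (fry adjusted p = 0.28) and immature or disallowed genes were gained (0.0022). With an estimated correlation, 0 of 48 list tests passed, against 22.

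Counts moved by over 1.5 times as follows. With a mean of at least 5 RPKM, 7900 genes were tested, and 3740 (2855 higher) changed against beta, 830 (371 and 459) against delta and 4347 (3245 lower) between beta and delta, with 80 and 7 outside both. Median-of-ratios scaling gave 3624 and 3395 against beta, 3623 and 3865 for beta against delta, and 53 lower than both; quantile normalization gave 2701 and 3144, 3383 and 3171, and 105. On 8818 genes, limma-voom with the median-of-ratios factors in its library sizes gave 2605 and 2260, 2459 and 2716, and 120 and 49 outside both. The main test on those genes, without scaling, gave 700 lower against beta, 1100 (608 lower) against delta and 1008 higher for beta against delta, because fewer genes were tested. The limma-voom fit differs from this main test in scaling as well as in model, and these effects were not separated. A pseudocount of 0.1 left 145 higher than both and no filter 7 lower than both; these causes were not tested. The replicate block gave 29 lower than both and changed the calls of Pdx1 and 2 lists; list counts that it moved by 2 or more genes are given with the comparisons.

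Without 1 library, counts ranged from 4132 to 7086 against beta (3722 to 5957 higher, 410 to 1129 lower), 522 to 2055 against delta (269 to 862, 253 to 1193), with 853 to 1549 higher for beta against delta, and 72 to 318 higher and 2 to 45 lower than both. The lone library left in a group is assumed to vary like the others.

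The position of beta-enriched genes was 0.74 and 0.64 with pseudocounts of 0.1 and 3, 0.62 and 0.71 at 2-fold and 8-fold, 0.72 at a mean of 5 RPKM, 0.57 scaled, 0.43 linear and 0.32 linear and scaled. For delta-enriched genes these were 0.22 and 0.39, 0.22 and 0.34, 0.31, 0.37, 0.58 and 0.61. By pool they were 0.65 to 0.68 and 0.341 to 0.343. The planned edgeR and DESeq2 fits were not run, since the table holds no counts. Depth limits genes near 0.275 RPKM, where few reads stand behind a value.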

Other observations

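The tests of mixing, of dilution and of low counts were chosen after the result was seen; those of the nuclear and macrophage lists were fixed before their values were examined, for patterns already noticed. Genes in this part were chosen after their values were seen.

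Delta-cell and alpha-cell transcripts stood at different fractions of their delta level in transdifferentiated cells. In percent of the delta level of the same pool (male, then female), Hhex was at 39.9 and 32.1, Rbp4 at 32.2 and 29.5, Ghsr at 36.0 and 31.5, Sstr1 at 33.3 and 32.1, Ppy at 35.0 and 34.8 and Pyy at 30.5 and 30.7, while Sst was at 25.8 and 22.1 and the calcium-sensing receptor Casr at 62.5 in both. Casr was already at 9.52 and 18.3 RPKM in beta cells, so its percentage is no measure of delta-specific RNA. The alpha-cell genes Gcg (11.1 and 14.9) and Irx1 (9.17 and 14.5) were lower, but Irx2 was at 32.9 and 36.4. Which cells of the YFP-positive sort the transcripts of other islet cell types came from was not tested. Beta-cell genes were put on another measure, which cannot be compared directly with these percentages. As a share of the way from the delta to the beta level, Mafa was at 0.141 and 0.341, Ucn3 at 0.291 and 0.359, Ins2 at 0.277 and 0.427, Papss2 at 0.813 and 0.684, the prohormone convertase Pcsk1 at 1.11 and 0.764, and Prlr at 1.69 and 1.30. After scaling these shares were lower, with Mafa at 0.0999 and 0.274 and Prlr at 1.17 and 1.04.

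Transdifferentiated libraries held beta and delta transcripts at intermediate levels, as a mixture of sorted beta and delta cells would. Such a mixture needs 1 beta share from both kinds of gene, but at 8-fold or more the share was 0.422 (male) and 0.386 (female) from beta-enriched and 0.614 and 0.653 from delta-enriched genes, a mean difference of 0.229 (0.0822 to 0.3503 over the 8 combinations of fold, level and scaling tried, in the same direction in both pools). Without the marker lists of other cells the shares were 0.425 (male) and 0.427 (female) against 0.608 and 0.646. Dilution of delta-enriched transcripts by 1 common factor was not decided. Per-gene shares agreed between the pools over 36 beta-enriched genes (Spearman rho 0.914) and over 65 delta-enriched genes without markers of other cells (rho 0.808). The permutation p was 1e-05 for each, the smallest that 100000 resamples can give, across genes that are not independent replicates. A share also depends on each gene's ratio of beta to delta level, which the pools have in common. Such agreement can therefore arise under dilution too. The first rule for delta-enriched genes, the spread of their log2 ratios (0.407 and 0.516), had not decided, and the correlation was added after its value was seen. For beta-enriched genes the spread of log2 ratios to the beta level was 0.635 (male) and 0.830 (female), and 0.734 and 0.752 after scaling. This measure does not use the delta level, and 1 common factor would leave it small. With an order of genes shared by the pools, these spreads argue against 1 common factor for the beta-enriched genes used. Dilution of delta-enriched transcripts by 1 common factor and an intermediate state of the double-positive cells stay open. So does a mixture of delta cells or doublets with insulin-positive cells that differ from the sorted beta population. Those cells may be low in Mafa and Ucn3. These data do not separate the explanations that stay open.

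Among genes higher than in both reference populations was the nuclear transcript Neat1 (62.2 and 56.1 RPKM, against 14.7 and 16.0 in beta and 25.3 and 16.1 in delta libraries). Malat1 and Meg3, 2 other nuclear transcripts, were at 105% and 149% and at 110% and 186% of the delta level (male, female), against 246% and 348% for Neat1. Gipr, the incretin receptor, and Mlxipl, a glucose-responsive factor, were also above both and were picked by eye, with no list of such genes tested. Against low counts in the shallower libraries as the whole cause, 70 of 7900 genes with a mean of at least 5 RPKM were above both after scaling, 48 of them among the 226. This does not settle the point. The mean includes the transdifferentiated libraries, and short genes can reach it on few reads. A higher share of nuclear or unspliced RNA may account for part: 12 measured genes of a nuclear list had scaled medians of 1.51 above beta and 0.373 above delta (camera p = 1.41e-07 and 6.78e-04, or 0.16 and 0.31 with an estimated correlation), although 0 of 12 passed singly against delta cells. In beta against delta cells the scaled median was -1.16, with 12 of 12 lower. Much of the 1.51 is therefore a difference that delta cells also show, and only the 0.373 bears on being above both.

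Immune transcripts were highest in the beta libraries. Macrophages in the mCherry gate are a candidate source: 9 of 10 macrophage genes not used before, such as Laptm5 (1.86 and 2.58 RPKM) and Itgb2 (1.35 and 2.29), were higher in both beta libraries than in all 4 others, next to abundant Cd74 (72.5 and 73.9) and Lyz2 (5.82 and 7.99). How macrophage RNA would enter a gate set on a nuclear insulin reporter was not tested. Reporter protein taken up and cells sorted together are among the possible routes. C1qa did not follow C1qb and C1qc (34.9 and 40.5 RPKM in beta, 59.3 and 76.9 in delta libraries, a lower call in beta cells that was lost after scaling, adjusted p = 0.062), and no biological explanation was tested.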
